A study of Mus musculus with 2 samples.

How the data were processed

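Libraries made from total RNA of stomachs of mouse embryos at 14.5 days of gestation (E14.5), of strain B6NCrl, were sequenced. Per the labels, each of the 2 libraries came from a single stomach of 1 pup, and the 2 samples were collected on day 15 and day 17 of the same month. They are biological replicates 1 and 2 of 1 group, and the labels give no second condition, so no comparison between conditions was possible. The labels call the sex pooled male and female, which is at odds with a single pup per sample. RNA was extracted with a mirVana kit, the starting quantity was 10 ng, RNAs longer than 200 nt were kept, and a Smart-seq protocol document was linked to both samples, per the labels. Spike-in RNAs of known sequence were added, per the labels. How far the library step kept RNAs without a poly(A) tail was not tested, so levels of such RNAs may not be those of the tissue.

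The authors deposited, for each library, 1 table of genes and 1 of transcripts. Per the deposited notes and the labels, the genome build was mm10 and the annotation GENCODE M4. The programs that aligned and counted the reads are not given in the sources used here, nor is it stated whether counting used strand. Reads of a gene and of its antisense partner therefore cannot be told apart. The deposited expected counts are estimated read numbers per gene, not normalized and not always whole, because reads shared by several genes were split between them. The deposited TPM values scale to a fixed total that includes the spike-ins, so a larger spike-in share lowers every gene's TPM. A second TPM column, the deposited posterior mean, served as an alternative. The deposited FPKM values were not used here. The deposited percent values in the transcript tables give a transcript's share of its gene. Each table also holds 96 spike-in sequences and 26248 entries with a number in place of a gene name. These numbered entries stayed out of library sizes and comparisons, and took 15.47 counts in replicate 1 and 25 in replicate 2. Of 43346 Ensembl gene identifiers, 42462 matched a symbol in GENCODE M21, and the 884 others took 0.191% and 0.19% of the counts. Gene positions come from GENCODE M21, which uses the same mm10 assembly.

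Total expected counts were 25072242 in replicate 1 and 25599910 in replicate 2, of which 23668322 and 23882647 fell on genes. At this depth a count of 0 in a library allows up to 3 counts. Intervals and floors cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. Values are given as mean ± SD over the 2 libraries (n = 2), and this spread holds the difference between embryos as well as that between library preparations. A gene was called detected at TPM 1 or more in both libraries.

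Ratios between the libraries were computed from expected counts of genes with TMM library sizes from edgeR 4.0.16 in R 4.3.3, as the log2 of replicate 2 over replicate 1 with 0.5 added to each count. With 1 library on each side there is no p-value for any gene. Genes with a mean count of 100 or more and a ratio over 2-fold were counted. The coefficient of variation was the square root of edgeR's common dispersion, with an intercept-only design, on expected counts rounded to whole numbers and genes with a mean count of 10 or more. Its interval and that of the correlation come from bootstrap samples of genes, 100 for the dispersion and 200 for the correlation. The correlation was taken on log2(TPM + 1), over genes at TPM 1 or more in at least 1 library. A chi-square test on rounded counts compared the 2 libraries to see if they could be 1 library deposited under 2 names.

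Before the data were examined, 37 gene lists for cell types, pathways, neighbouring organs and signs of RNA quality were fixed, with the rule for the genes that are named. The rule took the 15 most abundant nuclear genes with an established symbol, leaving out ribosomal protein genes. It also took the 3 most abundant members of each list, 14 genes named in any case, the 10 highest and 10 lowest ratios between the libraries among genes with an established symbol and a mean count of 100 or more, and the top transcript of 12 genes. Some genes that the rule takes are not reported here. Other genes that are named, such as list members with the widest ratios, were chosen after their values were seen. For lists with at least 3 members at a mean count of 10 or more, the median ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries and is not a test of a condition, and members of a list are not independent. Alternatives were DESeq2 1.42.0 size factors, the deposited TPM ratio, scaling on spike-in counts, other filters, pseudocounts and thresholds, posterior mean TPM, TPM rescaled without spike-ins and mitochondrial genes, and each library alone. Scaling on spike-in counts in place of TMM moved every log2 ratio by -0.27, so ratios are relative to the typical gene.

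The procedure was tested on simulated counts for 43346 genes with the means of the real libraries, with 200 genes changed by known amounts. The simulated replicate 2 was set somewhat larger than the real library, and the same coefficient of variation was used for every gene. For the simulated replicate 2 against replicate 1, 97.9% of the genes changed by 1.5 on the log2 scale and 100.0% of those changed by 2.0 were called over 2-fold with the right sign, among 12859 genes with a mean count of 100 or more. Another 3 unchanged genes were called. A simulated coefficient of variation of 12.0% was recovered as 12.1% without the changed genes and as 15.6% with them. Of 100 lists of unchanged genes, 5 fell outside the central 95% of random lists. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.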

Results

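RNA-seq libraries made from total RNA profiled the E14.5 mouse stomach, a stage at which the organ's epithelium, mesenchyme and nervous system are being laid down. The single group held 2 libraries, each from the stomach of a different embryo, with 25072242 expected counts in replicate 1 and 25599910 in replicate 2. The design asks which genes the organ expresses and how far its 2 replicates differ.

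The stomach expressed a broad set of genes. Structural RNAs, cytoskeletal genes and haemoglobins were prominent among the most abundant nuclear genes, ribosomal protein genes left out. Values are means ± SD (n = 2). In all, 15137 genes were at TPM 1 or more in both libraries, of which 13271 were protein coding, 476 processed pseudogenes, 328 antisense genes and 235 long intergenic noncoding RNAs. Replicate 1 had 15832 such genes and replicate 2 had 15822, and 1380 reached the threshold in 1 library only. Among nuclear genes with an established symbol, ribosomal protein genes left out, the most abundant were the 7SL RNA genes Rn7s1 (7347 ± 734 TPM) and Rn7s2 (7346 ± 732 TPM), near-identical copies that share reads, so their separate levels are uncertain. Next among these nuclear genes were the noncoding RNA Malat1 (6048 ± 722 TPM), beta-actin Actb (5994 ± 0.566 TPM), the alpha-globin gene Hba-a2 (4811 ± 86.7 TPM), the elongation factor Eef1a1 (4543 ± 88.1 TPM), Ppia (4209 ± 46.8 TPM) and Tmsb4x (4052 ± 93.3 TPM). In replicate 1 Malat1 had 43983 counts for 5538 TPM, and the short gene Hba-a2 36433 counts for 4750 TPM. The TPM of Malat1 thus rests on a length close to that of Hba-a2, although its locus is far longer (chromosome 19, 5795690 to 5802672). The rank of Malat1 by TPM is therefore uncertain. The remaining 7 of the 15 were Ftl1 (3358 ± 137 TPM), Hist1h2ap (3093 ± 456 TPM), Ubb (2279 ± 17.4 TPM), Actg1 (2228 ± 6.58 TPM), Hbb-bs (2155 ± 27.1 TPM), Cym (2039 ± 159 TPM) and Ptma (1973 ± 94.96 TPM). Cym encodes chymosin, the milk-clotting protease of the neonatal stomach (ENSMUSG00000046213.9, chromosome 3, 107211293 to 107221732, minus strand). Hba-a2, Hbb-bs and Hist1h2ap have near-identical relatives with which reads may be split.

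Spike-ins took 13.2% ± 1.45 of TPM and ribosomal protein genes, with their pseudogenes, 8.28% ± 0.071. Mitochondrial genes took 3.50% ± 0.008, haemoglobin genes 1.11% ± 0.039 and replication-dependent histone genes 0.434% ± 0.056. The 10 most abundant of all nuclear genes in each library, predicted genes such as Gm42418 counted in, together held 6.60% ± 0.119. By expected counts, which do not divide by length, the spike-in share was 5.599% in replicate 1 and 6.71% in replicate 2.

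Epithelial genes were strongly expressed, and both glandular and stratified programmes were present. All 15 pan-epithelial genes were detected, led by the simple-epithelium keratins Krt8 (607 ± 56.1 TPM), Krt18 (331 ± 32.1 TPM) and Krt19 (317 ± 37.2 TPM), and the adhesion molecule Epcam stood at 255 ± 15.2 TPM. All 12 transcription factors of the gastric endoderm were detected, led by Klf5 (84.9 ± 8.78 TPM), Gata4 (33.5 ± 5.37 TPM) and Foxq1 (24.9 ± 4.93 TPM). The foregut regulator Sox2 (chromosome 3) was at 7.91 ± 0.389 TPM. All 10 genes of stratified forestomach epithelium were detected, with Krt15 (171 ± 17.7 TPM), Perp (156 ± 12.5 TPM) and Krt13 (81.6 ± 36.0 TPM) highest. Trp63, the master regulator of stratified epithelia, was at 36.1 ± 3.13 TPM. Of 14 products of the mature gastric gland, 9 were detected, led by the trefoil factor Tff1 (101 ± 1.22 TPM), the mucin Muc1 (43.7 ± 0.177 TPM) and the pepsinogen Pgc (30.1 ± 4.65 TPM). The proton pump subunits of parietal cells differed in level, with Atp4b at 12.5 ± 0.099 TPM and Atp4a at 1.57 ± 0.276 TPM. Of 13 enteroendocrine genes, 5 were detected in both libraries (8 in replicate 1 and 5 in replicate 2), led by Gast (7.57 ± 3.47 TPM), Ghrl (5.40 ± 0.799 TPM) and Chga (4.01 ± 0.396 TPM).

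Mesenchymal and muscle genes were abundant, with median levels of 137 and 131 TPM for fibroblast matrix genes and 143 and 127 TPM for smooth muscle genes in replicates 1 and 2. All 17 transcription factors of the stomach mesenchyme were detected, led by Tcf21 (289 ± 15.3 TPM), Meis1 (116 ± 0.438 TPM) and Foxf1 (116 ± 5.54 TPM). Barx1, a transcription factor of the stomach mesenchyme (chromosome 13), was at 101 ± 9.22 TPM and Nkx3-2 at 1.81 ± 0.460 TPM. All 15 fibroblast matrix genes were detected, with Col3a1 (1613 ± 88.4 TPM), Sparc (1236 ± 68.4 TPM) and Col1a1 (900.4 ± 68.5 TPM) highest. All 14 smooth muscle genes were detected, led by Acta2 (1900 ± 42.4 TPM), Actg2 (1068 ± 75.1 TPM) and Tpm2 (610.2 ± 42.1 TPM). The 4 genes of the interstitial cells of Cajal, the pacemaker cells of the gut, were all detected, led by Kit (51.6 ± 4.24 TPM), Ano1 (48.0 ± 1.45 TPM) and Etv1 (40.6 ± 1.78 TPM). Of 6 mesothelial genes, 5 were matched and all 5 were detected, with Upk3b (28.4 ± 3.46 TPM), Msln (19.8 ± 4.13 TPM) and Wt1 (16.0 ± 3.22 TPM) highest.

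Genes of the enteric nervous system, vessels and blood were present at lower levels, apart from the globins. All 7 neural crest and glial genes were detected, led by Ednrb (90.3 ± 8.61 TPM), Fabp7 (58.3 ± 1.52 TPM) and Erbb3 (20.3 ± 0.460 TPM). Of 19 neuronal genes, 17 were detected, led by Uchl1 (75.7 ± 1.41 TPM), Stmn2 (72.5 ± 1.63 TPM) and Gap43 (72.0 ± 0.127 TPM). All 14 endothelial genes were detected, led by Egfl7 (87.6 ± 5.86 TPM), Plvap (49.8 ± 0.983 TPM) and Esam (43.5 ± 0.757 TPM). Of 7 pericyte genes, 6 were detected, led by Kcnj8 (81.8 ± 3.36 TPM), Pdgfrb (32.5 ± 1.03 TPM) and Abcc9 (22.0 ± 1.81 TPM). Of 15 erythroid genes, 14 were matched and 11 detected, led by Hba-a2, Hbb-bs and Hba-a1 (1775 ± 110 TPM). All 13 macrophage genes were detected, with Lyz2 (56.0 ± 7.95 TPM), C1qb (52.3 ± 0.212 TPM) and Tyrobp (38.8 ± 4.14 TPM) highest.

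**Figure D1:**
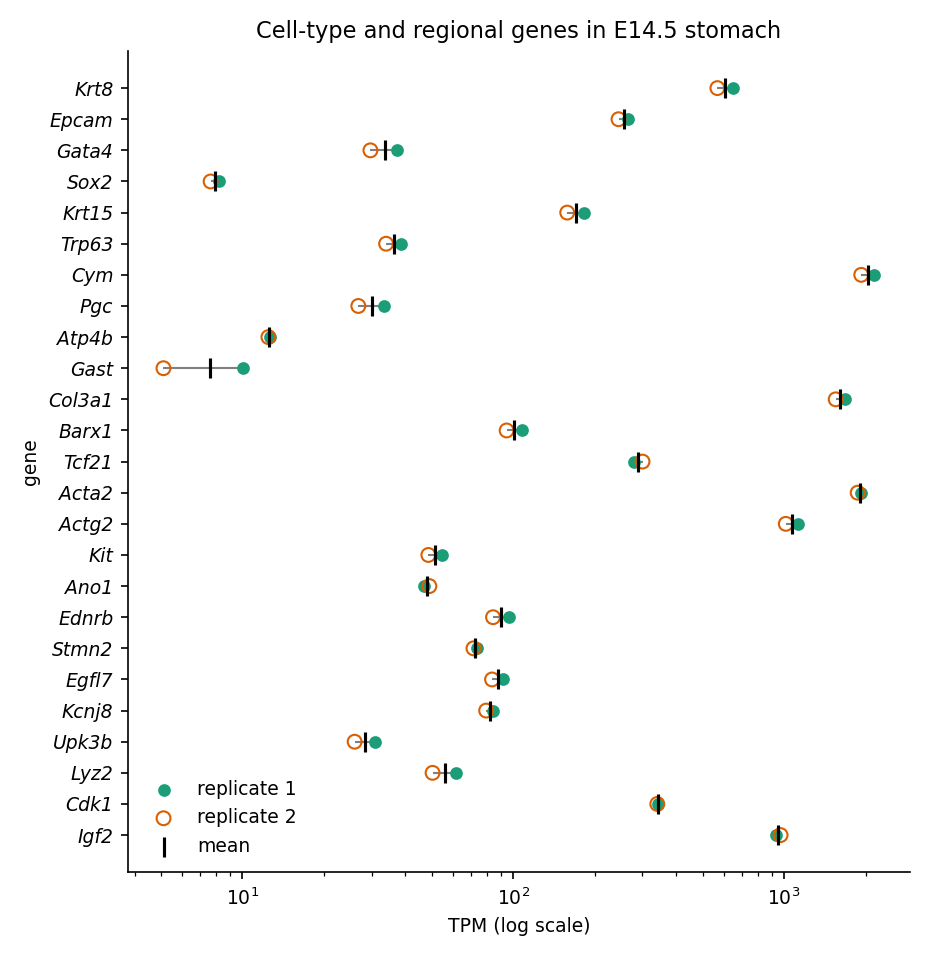
TPM on a log scale for genes of the epithelium, mesenchyme, muscle, nervous system, vessels and other groups, with 1 point per library and a bar at the mean. Gast lay at 10.0 TPM in replicate 1 and 5.11 in replicate 2, while Cdk1, at 341 ± 1.27 TPM, and Atp4b, at 12.5 ± 0.099 TPM, were almost level.

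Components of the signalling pathways that pattern the stomach were detected, most of them in both libraries. All 9 hedgehog pathway genes were detected, led by Ptch1 (40.3 ± 0.827 TPM), Smo (39.0 ± 5.23 TPM) and Gli3 (25.3 ± 0.361 TPM), and the ligand Shh was at 3.69 ± 0.417 TPM. All 15 Wnt pathway genes were detected, with Sfrp2 (129 ± 3.73 TPM), Sfrp1 (101 ± 3.25 TPM) and Wnt5a (30.1 ± 1.19 TPM) highest. The 15 genes of the FGF and BMP pathways were all detected, led by Id2 (315 ± 14.9 TPM), Id3 (295 ± 3.85 TPM) and Fgfr2 (129 ± 0.976 TPM). Of 14 retinoic acid genes, 12 were detected, led by Dhrs3 (100.04 ± 9.64 TPM), Crabp1 (84.3 ± 12.2 TPM) and Aldh1a2 (74.4 ± 5.08 TPM). All 10 Notch pathway genes were detected, with Hes1 (56.2 ± 2.25 TPM), Notch2 (26.9 ± 1.39 TPM) and Notch1 (22.8 ± 1.51 TPM) highest. The 15 fetal and imprinted growth genes were all detected, led by H19 (1032 ± 0.170 TPM), Igf2 (953 ± 25.6 TPM) and Mest (916 ± 74.8 TPM).

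Outside the pancreas list, where the libraries parted, genes of neighbouring organs were low apart from Apoa1 and Ttr of the liver list. Of 8 intestinal genes, 5 were detected, the highest Cdh17 (5.51 ± 0.863 TPM), Vil1 (5.09 ± 1.09 TPM) and Isx (3.57 ± 0.134 TPM), while the intestinal regulator Cdx2 was at 0.905 ± 0.078 TPM. Of 10 liver genes, 6 were detected, led by Apoa1 (53.6 ± 2.66 TPM), Ttr (16.9 ± 2.24 TPM) and Afp (5.75 ± 1.33 TPM). None of the 5 lung genes was detected, Sftpc and Sftpd being the highest at 0.160 ± 0.113 and 0.095 ± 0.134 TPM, and Nkx2-1 had 0 counts in both libraries, which allows up to 3 counts in each. Of 12 skeletal muscle genes, 4 were detected, led by Mylpf (5.25 ± 0.622 TPM), Acta1 (4.42 ± 1.99 TPM) and Tnnt3 (1.75 ± 0.127 TPM). Of 13 pancreas genes, 12 reached TPM 1 in replicate 1 and 5 in replicate 2, among them Cela1, Nkx6-1 and Pdx1.

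Proliferation genes were high, and the stress lists were detected at varied levels. All 18 cell cycle genes were detected, led by Cdk1 (341 ± 1.27 TPM), Birc5 (222 ± 5.38 TPM) and Pcna (208 ± 3.71 TPM). Of 14 immediate early genes, 11 were detected, with Ier2 (58.6 ± 6.79 TPM), Jun (44.2 ± 5.03 TPM) and Btg2 (43.8 ± 4.13 TPM) highest. The 15 hypoxia and glycolysis genes were all detected, led by Ldha (1266 ± 79.3 TPM), Eno1 (1155 ± 61.9 TPM) and Aldoa (561 ± 9.73 TPM). Of 8 heat shock genes, 7 were detected, with Hspa8 (1702 ± 184 TPM), Hsp90aa1 (616 ± 45.4 TPM) and Hspb1 (172 ± 12.6 TPM) highest. Of 17 replication-dependent histone genes, 16 were detected, led by Hist1h4d (285 ± 28.3 TPM), Hist1h2bc (86.1 ± 5.49 TPM) and Hist1h1e (35.4 ± 0.905 TPM), all with close paralogs. The 6 polyadenylated variant histones were all detected, led by H3f3a (1818 ± 54.4 TPM), H3f3b (1464 ± 74.2 TPM) and H2afz (1255 ± 33.5 TPM). Of 6 long structural noncoding RNAs, 5 were detected, with Malat1, Rn7sk (544 ± 2.47 TPM) and Rpph1 (101 ± 11.1 TPM) highest. Levels of replication-dependent histone and structural RNAs may depend on how the library step captured RNAs without a poly(A) tail. All 13 mitochondrial mRNAs were detected, led by mt-Atp6 (6381 ± 110 TPM), mt-Atp8 (5470.0 ± 314 TPM) and mt-Cytb (3375 ± 18.3 TPM).

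Among 12 genes chosen for their known isoforms, 11 had the same top transcript in both libraries. The tropomyosin transcript ENSMUST00000107914.5, with 9 exons, took 95.7% ± 0.070 of Tpm2, and ENSMUST00000023538.8, with 32 exons, took 99.1% ± 0.140 of the kinase gene Mylk. Myl6, counted among the 11, had 1 annotated transcript, so its agreement was fixed in advance. Top transcripts held smaller shares in Actn1 (61.9% ± 1.86), Cd44 (51.4% ± 0.160), Ctnnd1 (49.0% ± 0.520), Enah (42.7% ± 1.53), Cald1 (38.5% ± 0.670), Tpm1 (35.9% ± 1.02) and Fgfr2 (31.9% ± 0.340). For Fn1 the top transcript, ENSMUST00000185408.2, is annotated as a retained intron and took 38.3% ± 1.76. In Trp63 the transcript highest on average, ENSMUST00000115306.3, took 46.1% in replicate 1 and 34.3% in replicate 2.

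Among genes with an established symbol, the 2 replicates differed most at sex-linked genes and at genes of the exocrine pancreas. The Y-linked genes Ddx3y, Eif2s3y and Uty had 2550, 1454 and 1256 counts in replicate 1 and 0 in replicate 2, so they were at least 863-fold, 492-fold and 425-fold lower there. The Y-linked demethylase gene Kdm5d had 1299 and 2 counts, a ratio of 660 (95% counting interval 182 to 5452). Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), had 13.5 counts in replicate 1 and 32038 in replicate 2, 2427-fold higher (1419 to 4558). The pancreatic lipase-related gene Pnliprp1 (chromosome 19, 58728887 to 58744169) had 4774 counts in replicate 1 and 1 in replicate 2, a ratio of 4848 (870 to 191523).

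Chymotrypsinogen Ctrb1 (chromosome 8, 111686519 to 111691010) had 2020 counts in replicate 1 and 1 in replicate 2, a ratio of 2051 (368 to 81061). The amylase genes Amy2a5, Amy2a2, Amy2a3 and Amy2a4, near-identical copies whose separate counts are uncertain, had 759, 749.5, 749.5 and 749.5 counts in replicate 1 and 0 in replicate 2, at least 257-, 254-, 254- and 254-fold lower. Other members of the pancreas list followed, with the carboxypeptidase gene Cpa1 at 2203 and 30 counts. The list's 12 members with a mean count of 10 or more all had lower values in replicate 2, with a median log2 ratio of -5.02, or -4.99 with the member at 0 counts set to 3 counts. Pdx1, at -0.60, and Nkx6-1, at -0.59, differed least. Neurog3, an endocrine regulator of both pancreas and gut, had 80.9 counts in replicate 1 and 11 in replicate 2.

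Of genes with an established symbol, those highest in replicate 2 differed by less than those lowest, apart from Xist. Tsix, antisense to Xist, had 12.02 and 375 counts, but its reads cannot be told from those of Xist without strand. The mitochondrial gene mt-Nd4l, which overlaps mt-Nd4, had a log2 ratio of 2.02, and the X-linked paralogs Xlr3a and Xlr3b, near-identical copies, had 1.76 and 0.93. Mpo, the myeloperoxidase of granulocytes, had a log2 ratio of 1.06 (70.7 and 150 counts). The rest of the 10 highest with an established symbol were Dbndd2 (0.89), Pak7 (0.88), the X-linked noncoding RNA Jpx (0.85) and Zc3h12b (0.84), also on X. Dbndd2 overlaps Gm20458, which had a log2 ratio of -1.95 and was named after its value was seen, so the split of reads between them is uncertain.

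Across genes with a mean count of 100 or more, 38 of 12761 lay over 2-fold apart, 9 higher in replicate 2 and 29 higher in replicate 1. Those 38 held 5 members of the pancreas list, all 4 Y-linked genes and 1 of the X-linked list, and 28 lay over 2-fold apart once those lists were left out, a choice made after seeing the data. The 28 still held Pnliprp1, Clps, the amylase genes, Tsix and Xlr3a, which were not members of the lists. Among the others were Spp1 (1317 and 141 counts), Gc and Serpina6. The near-identical pair Gm14288 (-6.53) and Gm14440 (9.38) was among them too, and its reads may have been split differently in the 2 libraries. Of the 28, 20 were higher in replicate 1 and 8 in replicate 2. The count depended on the filter, with 631 genes at a mean count of 10 or more, and on scaling, with 63 when spike-in counts set the sizes, 5 of them higher in replicate 2. For 95% of genes the log2 ratio lay within 0.38 of 0. The coefficient of variation between the 2 libraries, 1 value shared by all genes, was 11.3% (95% interval from a bootstrap of genes, not of embryos, 9.23 to 12.8, 17532 genes). It was 8.59% without the pancreas, Y-linked and X-linked lists, which still counts in Pnliprp1, Clps, the amylase genes, Tsix and Xlr3a. Pearson's r of log2(TPM + 1) across 16517 genes was 0.978 (0.976 to 0.981) and Spearman's rho 0.981, where genes are not independent replicates. Counts of the 2 libraries differed by more than sampling noise (chi-square 153110 on 17509 degrees of freedom), so they were kept as separate libraries. Over 47 spike-ins with a mean count of 100 or more, the log2 ratio had an SD of 0.16 (0.11 to 0.21) around a median of 0.26, against 0.57 over 784 genes matched on count. Their robust spreads, which give extreme genes little weight, were 0.11 and 0.13. At a mean count of 1000 or more the SDs were close, 0.089 for 27 spike-ins and 0.101 for 384 matched genes.

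**Figure D2:**
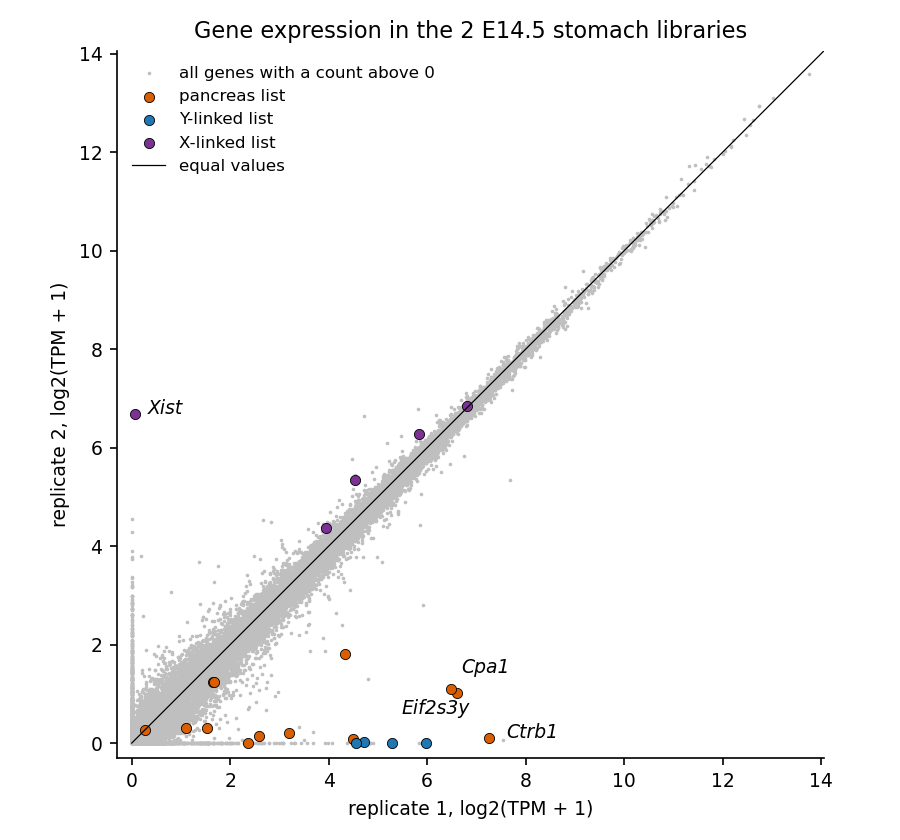
Expression of each gene in replicate 1 against replicate 2, as log2(TPM + 1), with members of the pancreas, Y-linked and X-linked lists in colour and a line at equal values. Xist lay at 0.05 TPM in replicate 1 and 101.8 in replicate 2, and Ctrb1 at 152 and 0.07.

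Of 36 gene lists that could be placed, 16 had a median log2 ratio outside the central 95% of random lists, where 1.8 would be so for lists of independent genes. Lower in replicate 2 beside the pancreas list were the Y-linked list, with a median of -11.42 over 4 genes, or -8.99 with the 3 members at 0 counts set to 3 counts, and the enteroendocrine list, with -0.91 over 10 genes, all lower. In the latter, Gast had -0.90, Gcg -1.72 and Neurog3 -2.85, and the pancreas list, with whose tissue several of these genes are shared, was lower as well. The stratified forestomach list had a median of -0.26, below all 10000 random lists, with all 10 members lower, among them Krt13 (-0.89), Krt4 (-0.72) and Dsg3 (-0.55). The mesothelial list had -0.26 (percentile 0.14, 5 of 5 lower), with Wt1 at -0.40 and Msln at -0.36. Smaller shifts were those of the immediate early (-0.18, percentile 0.68), hypoxia and glycolysis (-0.15, percentile 0.06), heat shock (-0.13, percentile 1.52), pan-epithelial (-0.09, percentile 0.46) and fibroblast matrix lists (-0.08, percentile 1.1). The heat shock list lay inside the central range at a mean count of 100 or more, and the fibroblast matrix list as deposited TPM ratios and when random lists were matched on length too.

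Higher in replicate 2 was the X-linked list, with a median of 0.51 and all 5 members higher, from Ddx3x (0.08) to Kdm5c (0.67) and Xist. The liver list had 0.54 (percentile 99.9), with Alb, the albumin gene, at 44 and 122 counts, but only 4 of 7 members higher, and -0.03 at a mean count of 100 or more. Long structural noncoding RNAs had 0.29 (percentile 99.97) and replication-dependent histones 0.22 (percentile 99.7). Cell cycle genes had 0.04 (percentile 98.7) and mitochondrial mRNAs 0.05 (percentile 98.2), medians that were -0.01 in both as deposited TPM ratios. The cell cycle list stayed outside the central range there, while the mitochondrial list lay inside it, as it did with length matching. Scaling on spike-in counts moves every list alike by -0.27, which puts the histone, cell cycle and mitochondrial medians below 0 and leaves their place among random lists as it was. The other lists lay inside, with medians from -0.25 for intestinal epithelium and -0.16 for gastric gland products to 0.08 for erythroid genes. With 1 library on each side these shifts compare 2 embryos and their library preparations, and carry no replicate check.

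**Figure D3:**
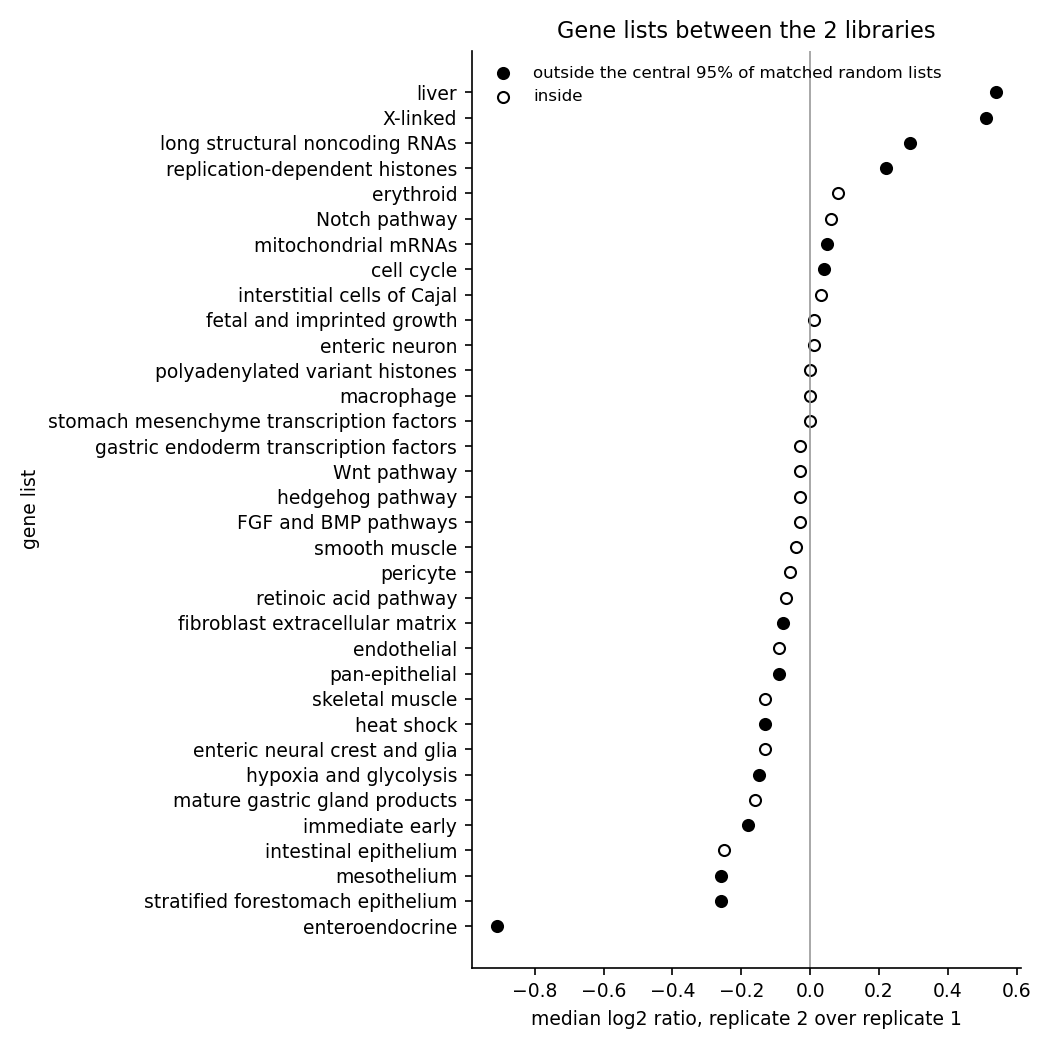
Median log2 ratio of replicate 2 over replicate 1 for each gene list with at least 3 members at a mean count of 10 or more, filled where it lay outside the central 95% of matched random lists. The pancreas (-5.02) and Y-linked (-11.42) lists are left out of the plot for scale, and the liver list lay highest at 0.54 and the enteroendocrine list lowest at -0.91.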

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

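No test was run for the values in this part, and it holds no weighing of explanations. Entries identified by numbers in place of gene names, which no comparison used, held counts above the 3 that a count of 0 allows. They took 15.47 expected counts in replicate 1, over 5 entries, and 25 in replicate 2, over 4 entries. Set against total counts of 25072242 and 25599910, these values are small.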

How the results depend on the processing

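Leaving out the pancreas, Y-linked and X-linked lists, and with them the genes furthest apart, was chosen after seeing the data, and the other settings were fixed before. No paired analysis was possible because there is 1 group. Leaving out a replicate gives no ratio between the libraries, and so no value for the correlation, the coefficient of variation, the gene count over 2-fold, the spike-in spread or the list shifts. Shares of expected counts in place of TPM moved all 7 parts of the library composition, with means of 6.15% for spike-ins, 2.00% for mitochondrial genes, 3.19% for ribosomal protein genes, 0.381% for haemoglobin genes, 0.123% for replication-dependent histone genes, 2.12% for Gm42418 and Gm26917 together (1.57% of TPM), and 5.31% for the 10 most abundant of all nuclear genes, chosen by counts. By construction counts do not divide by length, which lowers the share of short RNAs. Pearson's r across genes was 0.937 with a pseudocount of 0.1, 0.992 with no filter on low values and 0.975 with a filter at TPM 10. The coefficient of variation was 13.1% with no filter and 8.59% without the 3 lists. The number of genes over 2-fold apart was 63 with scaling on spike-in counts, 631 at a mean count of 10 or more and 5064 with no filter. The last 2 settings admit genes with few counts, for which counting error alone is large. The SD of the spike-in ratios was 0.36 at a mean count of 10 or more and 0.089 at 1000 or more, beside 0.64 and 0.101 for matched genes. The liver list's median log2 ratio turned to -0.03 at a mean count of 100 or more, since fewer genes entered. As deposited TPM ratios, the medians of the cell cycle list and of the mitochondrial mRNAs turned to -0.01 each. Spike-ins took 12.1% of TPM in replicate 1 and 14.2% in replicate 2, which lowers every gene's TPM ratio. The turn is therefore at least partly an offset common to all genes. The number of lists outside the central 95% was 16 with DESeq2 size factors, 14 with TPM ratios, 15 of 34 at a mean count of 100 or more, 15 when random lists were also matched on length and 13 of 33 without the 3 lists and the 20 furthest genes. Of the 16 lists, 14 were again outside with length matching and 13 at a mean count of 100 or more. The enteroendocrine list could not be placed at that filter, because only Chga and Chgb passed it. Its shift therefore rests mostly on genes with fewer counts. Single lists moved inside the central range 6 times and outside it 3 times, counted over lists and settings. The fibroblast matrix list and the mitochondrial mRNAs moved inside with TPM ratios and with length matching, and the liver and heat shock lists at a mean count of 100 or more, where the endothelial and erythroid lists moved outside, the endothelial list also with length matching. Mpo fell under 2-fold, at 0.91 as a TPM ratio and 0.79 under spike-in scaling, and Dbndd2 passed it at 1.01. TPM of named genes moved by more than 1 SD in 129 values, 97 of them when TPM was rescaled without spike-ins and mitochondrial genes and 32 as posterior means, as did 17 shares of top transcripts. The number of detected genes, the number of detected members summed over lists and the number of lists outside the central range kept within 1.5 times under each alternative tried. Single lists did not all do so, since without replicate 2 the enteroendocrine list went from 5 to 8 detected members, the pancreas list from 5 to 12 and the Y-linked list from 0 to 4.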

Other observations

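The tests on sex pooling, the 4 X-linked genes, the liver and intestinal lists, the genes Gc, Serpina6 and Cps1, shared reads and the overall epithelial share were chosen only after the results were seen, while those on the second pancreas list and the basal and differentiation lists were fixed before their values were looked at. The Hox genes, transcription factors that mark position along the body axis, were chosen after the data had been opened. Of 18 genes in paralog groups 1 to 6, 15 were at TPM 1 or more in both libraries, with a median of 7.22 TPM. Hoxa5 (19.3 ± 1.85 TPM), Hoxc4 (18.7 ± 2.08 TPM), Hoxb2 (18.3 ± 1.91 TPM) and Hoxb5 (16.7 ± 0.728 TPM) were the highest (SD, n = 2). Of 16 genes in groups 9 to 13, Hoxa9 alone was detected, at 1.33 ± 0.255 TPM. Between them, Hoxa7 stood at 11.5 ± 0.163 TPM and Hoxb7 at 8.45 ± 3.16 TPM.

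Most genes of the pancreas list, and the exocrine genes Clps and Pnliprp1 outside it, were far lower in replicate 2 than in replicate 1, where Clps, Pnliprp1 and the list member Ctrb1 stood at 205, 186 and 152 TPM, though 5 of 13 members of the list reached TPM 1 in replicate 2 as well. A second list of 14 pancreas genes had a median log2 ratio of -2.55 over the 7 members with enough counts. All 7 were lower in replicate 2, which is what pancreatic tissue or RNA in the replicate 1 sample predicts. Slc38a5 (-0.07) differed least. The first list's shift was already known, and a gene high in replicate 1 alone can pass the count filter. The second list is therefore weak separate support, and it cannot tell pancreatic tissue from carried-over RNA. Splitting of reads between copies is argued against by the whole-number counts (within 0.001) of 11 of 12 pancreas genes, Rbpjl being the exception. Tissue of other neighbouring organs was first read as argued against by the liver list's median of 0.54, a reading changed to open after the value was seen because 3 of 7 members were lower, among them neither Alb (44 and 122 counts) nor Afp (161 and 238), while the intestinal list had -0.25 with 4 of 6 lower, and Gc (-5.05), Serpina6 (-4.09) and Cps1 (-2.26), which liver also expresses, were far lower. A piece of pancreas dissected with the stomach is a candidate explanation, as is RNA carried over from another sample; the design names no biological difference between the replicates, so none was tested.

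Y-linked counts lay almost only in replicate 1 and Xist counts almost only in replicate 2, while the labels call both samples pooled male and female. Pools of both sexes are argued against, since Xist in replicate 1 was 0.0427% of its level in replicate 2 and Y-linked counts in replicate 2 were 0.03% of those in replicate 1 (2 against 6559 counts). The X-linked genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x, which often escape silencing, had a median log2 ratio of 0.49, but they are the X-linked list without Xist, whose shift had been seen, so they add no separate support and the reading first given to them was withdrawn. A male embryo in replicate 1 and a female embryo in replicate 2, as single pups would allow, would give such Y-linked and Xist counts. No separate test of that reading was run. Sex, embryo and collection day cannot be separated with 1 library each, and sex remains untested as a source of other differences.

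Genes of the stratified forestomach epithelium were lower in replicate 2, with a median log2 ratio of -0.26. A larger epithelial share in replicate 1 stays open, because the stratified median lay -0.17 from the pan-epithelial one of -0.09 (95% bootstrap interval -0.50 to -0.02, which excludes 0 but not -0.1, the bound to which the test was moved from 0 after its value was seen), and the list had been singled out for its shift. Further lists of 12 differentiation and 10 basal genes had medians of -0.03 and -0.13, about that of the pan-epithelial list. Of these genes, 7 of 12 and 8 of 10 were lower in replicate 2. Neither list repeated the size of the first list's shift of -0.26. A larger stratified share with no other change stays open as well. The difference of the differentiation and basal medians, 0.10 (-0.31 to 0.31), met the bound set beforehand. Lists that had not moved would meet that bound too, so meeting it gives no support. The interval of the difference, weighed only after the value was seen, is too wide to decide. Both intervals in this paragraph come from bootstrap samples of list members, which are not independent. They do not cover the spread between embryos or library preparations. Regional sampling of the stomach at dissection may differ between the 2 samples, and no biological explanation was tested.

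The gene pair Gm14288 and Gm14440 had 305 and 0 counts in replicate 1 and 2.85 and 337 in replicate 2, while their sums were 305 and 340.3. Median log2 ratios by gene length were 0.06 in the shortest of 8 length classes and between -0.03 and 0 in the others.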
